A study of Caenorhabditis elegans with 4 samples.

How the data were processed

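Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on embryos of the Caenorhabditis elegans strain OP317. This strain carries an integrated transgene that expresses NHR-28, a nuclear hormone receptor, fused to GFP and FLAG tags. Per the labels' protocols, worms were grown at 20 degrees Celsius, crosslinked with formaldehyde and sonicated. Protein-bound DNA was then collected with an affinity-purified antibody against GFP. A part of each extract was set aside before the immunoprecipitation as input DNA. Per the labels, the 4 libraries were 2 ChIP libraries and 2 input libraries, with replicates numbered 1 and 2 in each group. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

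The processed data were 3 peak lists, covering ChIP replicate 1, ChIP replicate 2 and the series as a whole. No values of the input libraries were analysed here, and no background level in input DNA could be set beside the peaks. Per the file headers, positions are on the genome build WormBase WS220, and per a column of the deposited files the peaks were called with PeakSeq. The PeakSeq version, the aligner, the read filters and how the input libraries served as control are not given in the sources used here. Whether the series-level list was called on reads pooled from both replicates is likewise not given. Each peak has 1-based start and end coordinates and a p-value or q-value from PeakSeq, as deposited by the authors; the files do not say which of these it is. It is called the caller value below, and a lower caller value is a stronger peak. All caller values in the 3 lists are under 0.001, and 1 is listed as 0. They depend on sequencing depth, so their level is not compared between lists, except that the series-level −log10 value minus the sum of the replicate values was compared between sets of peaks of the same lists. The read depth of the libraries is unknown, so no precision from read counts can be given for a single peak. The peaks of the series-level list carry numbers that run to 2366, of which 23 have no row. Those numbers lie between 978 and 2326. Peaks were ranked here by caller value and not by these numbers.

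The gene table at hand is of another assembly, WBcel235. Coordinates of different builds were not mixed, so no peak was assigned to a gene. The planned comparisons that need genes or sequence were not run: position relative to genes, distance to gene starts, non-coding RNA genes, gene lists, the loci of the transgene's genes, sequence motifs and GC content. Chromosome lengths of WS220 were not used here either. The plan was to leave out the tests of chromosome shares and of centres against arms in that case. They were run all the same, a departure decided after the data were seen. The highest peak end of any list on a chromosome stood in for its length, which gives 99.8 Mb in all over 6 chromosomes and can only understate a length. The plan named the binomial test for X alone, so the tests of the single autosomes were also added.

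Peaks of different lists were partners when they shared at least 1 bp. Chance overlap was estimated from 100000 random circular shifts of the other list within each chromosome (one-sided permutation test). The smallest p these can give is 1e-05. Differences of medians and correlations of −log10 caller values were tested with 100000 two-sided permutations. A caller value of 0 was set to the lowest value above 0 of its list. The share of peaks on a chromosome was compared with the chromosome's share of the summed length by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes, and by a Monte Carlo multinomial test with 100000 draws. The middle 50% of each chromosome was compared with its outer parts by an exact binomial test. Shares have 95% Clopper-Pearson intervals, which cover counting error only and treat peaks as independent, although neighbouring peaks are not. The main peak set was the series-level list.

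The comparisons of the peak lists with each other and their alternatives were fixed before the data were examined. Added after the data were seen, besides the chromosome tests, were X peaks by rank, peaks close together, the chromosomes of peaks without a partner, support by rank, the strongest 50, 100 and 200 peaks, peak widths, shifts of 5 to 50 kb, the filter on narrow and very wide peaks and the 10 kb clusters. The rule for the peaks named in the text was fixed beforehand, and its parts that need genes were not used: the 25 series-level peaks with the lowest caller values among those with a partner in both replicate lists, and the 3 strongest peaks of each replicate list with no partner in the other list. All other positions printed were chosen after their values were seen. Alternatives were an overlap of at least 50% of both peaks, midpoints within 200 bp, the stronger part of each list, equal numbers of peaks, peaks found in both replicate lists, and each replicate list alone. On simulated lists of 649 and 495 peaks with 247 planted partners, the overlap count came to between 248 and 250 in 5 runs. Of 100 pairs of unrelated simulated lists, 7 reached a p under 0.05. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.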

Results

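Binding of the tagged nuclear hormone receptor NHR-28 was mapped in C. elegans embryos by ChIP-seq with an antibody against GFP. Nuclear hormone receptors are zinc-finger transcription factors, many of which are regulated by small lipophilic ligands. The study's purpose, per its design text, was to locate where NHR-28 binds the genome in vivo. The deposited lists held 649 peaks for ChIP replicate 1, 495 peaks for ChIP replicate 2 and 2343 peaks for the series as a whole. The median peak was 291 bp wide in replicate 1, 281 bp in replicate 2 and 252 bp in the series-level list. Peaks covered 226 kb in replicate 1, 167 kb in replicate 2 and 776 kb in the series-level list, of which 36.8 kb belonged to a single interval on chromosome X. Peaks under 50 bp wide numbered 17 in replicate 1, 11 in replicate 2 and 174 in the series-level list. All peaks lay on the 6 nuclear chromosomes, at positions given on WS220.

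The first comparison asked whether both ChIP replicates marked the same sites. Of the replicate 2 peaks, 349 of 495 (70.5%, 95% Clopper-Pearson interval 66.3 to 74.5%) shared at least 1 bp with a replicate 1 peak. The same 349 sites were 53.8% (49.9 to 57.7%) of the 649 replicate 1 peaks. Random circular shifts gave a mean of 2.52 shared peaks, so the observed number was 139-fold above chance (permutation test, p = 1e-05, the smallest p possible). Strong peaks were shared almost without exception. All 50 of the strongest peaks of each list had a partner in the other list (100%, interval from 92.9%), as did 99 of the 100 strongest replicate 1 peaks and 98 of the 100 strongest replicate 2 peaks. Among the 200 strongest, 183 (91.5%) had a partner in either direction.

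Shared sites had stronger caller values than sites seen in 1 replicate. In replicate 1 the median −log10 caller value was 5.73 for the 349 shared peaks and 3.67 for the 300 peaks without a partner, a difference of 2.05. In replicate 2 the corresponding medians were 4.83 for the 349 shared and 3.55 for the 146 other peaks, a difference of 1.29. Both differences had a permutation p of 1e-05. All caller values in the lists are under 0.001, and a weak peak can lack a partner because of that limit alone. Some difference of this direction was therefore to be expected. Shared peaks were also wider, with medians of 336 bp against 253.5 bp in replicate 1 and 316 bp against 194 bp in replicate 2 (permutation p = 1e-05 in each). Across the 349 shared sites the −log10 caller values of the replicates were correlated, with Pearson's r = 0.80 and Spearman's rho = 0.66 (permutation p = 1e-05 for each). This is a correlation across peaks, which are not independent replicates. Peak starts differed between replicates by a median of 30 bp, as did peak ends.

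**Figure D1:**
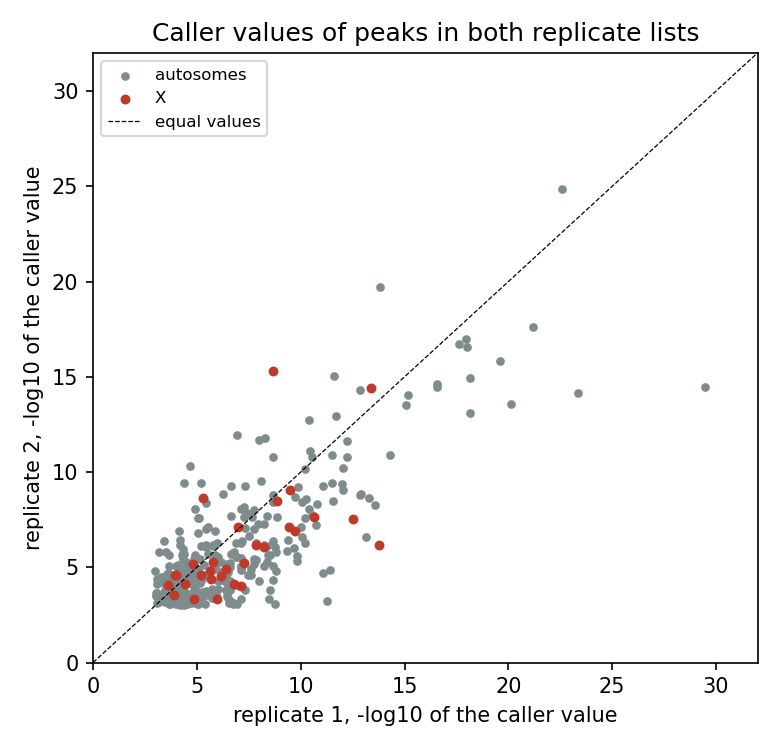
Each point is 1 of the 349 peaks shared by the replicate lists. The x axis gives the −log10 caller value in replicate 1 and the y axis that in replicate 2, red points lie on X, grey points on the autosomes, the dashed line marks equal values, and values rise together (Spearman's rho = 0.66).

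By series-level caller value, the strongest site shared by both replicate lists lay on chromosome V at 11313978 to 11314555. Its caller value was 2.74e-49 in the series-level list, and it ranked 3 in replicate 1 and 1 in replicate 2. A wide site on chromosome IV at 14032486 to 14034580 (2095 bp) followed with 6.76e-47, ranking 1 in replicate 1 and 13 in replicate 2. The sites on chromosome I at 13475415 to 13475878 and at 8259341 to 8259769 had caller values of 2.85e-42 and 2.03e-38. Chromosome X held a site at 11605391 to 11606412 with a caller value of 1.33e-39. The next sites were on chromosome V at 19642946 to 19643400 (2.27e-38), chromosome IV at 11025803 to 11026388 (2.17e-36), and chromosome V at 8500348 to 8500742 (4.45e-36) and 15873748 to 15874159 (7.98e-36). Chromosome V also held a site at 1627265 to 1627622 with 4.54e-35. By the same value, the leading shared sites on chromosomes III and II were at 10989354 to 10990051 (6.70e-34) and at 14804219 to 14804815 (4.19e-32). The 25 strongest shared sites comprised 6 on V, 5 each on I, III and X, 3 on IV and 1 on II. Their widths ran from 316 to 2095 bp with a median of 516 bp, and 19 of the 25 ranked within the first 50 peaks of both replicate lists. The remaining sites fell no lower than rank 74 in replicate 1 and rank 108 in replicate 2. The count on X has a limit. Over peaks in all 3 lists, series-level −log10 values exceeded the sum of the replicate values by a median of 4.79 on X and 1.08 on the autosomes. The series-level ranks of the 5 X sites are therefore not on the same footing as those of the autosomal sites.

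Ranking by the replicate lists gave other leading sites in places. The site on III at 7446777 to 7447880 ranked 2 in replicate 1 and 16 in replicate 2 but 164 in the series-level list (4.02e-13), and that on V at 5284004 to 5285459 ranked 8 and 20 but 545 (1.86e-07). Starts and ends together differed between replicates by only 2 bp at the site on III and 3 bp at that on V. Both are among the 7 held sites with like ends described under Other observations. Their replicate ranks are therefore not evidence of strong binding. Some of the 25 sites also differed in rank between replicates. The X site at 14525428 to 14526337 ranked 74 in replicate 1 and 8 in replicate 2. In the opposite direction, the X site at 6296272 to 6296787 ranked 18 in replicate 1 and 108 in replicate 2, and the site on chromosome I at 4701012 to 4701894 ranked 22 and 96. With 1 library per replicate these rank differences have no test.

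The strongest replicate 1 peaks with no partner in replicate 2 lay on chromosome IV at 5753281 to 5753752 (rank 70 of 649), on chromosome III at 4281990 to 4282544 (rank 101) and on chromosome I at 9382791 to 9383127 (rank 109). The strongest replicate 2 peaks with no partner in replicate 1 lay on chromosome V at 15431172 to 15433231 (rank 79 of 495, 2060 bp wide), on chromosome II at 11967546 to 11967921 (rank 83) and on chromosome III at 11316877 to 11317203 (rank 120). Each of these 6 sites had a partner in the series-level list. The chromosomes of the 300 replicate 1 peaks and 146 replicate 2 peaks without a partner did not differ detectably (permutation test of the chi-square of 10.7, p = 0.056).

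The second comparison set the series-level list against the replicate lists. The series-level list contained 613 of the 649 replicate 1 peaks (94.5%, interval 92.4 to 96.1%) and 477 of the 495 replicate 2 peaks (96.4%, interval 94.3 to 97.8%). Chance overlap was 11.4 and 8.48 peaks (permutation p = 1e-05 for each). Conversely, 343 of the 2343 series-level peaks (14.6%, interval 13.2 to 16.1%) were found in both replicate lists. A further 266 (11.4%) were found in replicate 1 only, 134 (5.72%) in replicate 2 only, and 1600 (68.3%, interval 66.4 to 70.2%) in neither. The median −log10 caller value was 11.96 for peaks found in both replicate lists and 4.05 for all others, a difference of 7.92 (permutation p = 1e-05). The median width was 412 bp for peaks found in both lists and 210.5 bp for peaks found in neither. The series-level list covers the same series as the replicate lists, so the lists are not independent. High overlap and stronger values of peaks in both replicate lists were therefore to be expected, and neither is separate evidence for the sites.

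Support in both replicate lists fell steeply with rank. Of the 200 strongest series-level peaks, 190 (95%) were in both replicate lists and 2 were in neither. In ranks 201 to 400 the number in both lists was 112 (56%), in ranks 401 to 600 it was 30 (15%), and in ranks 601 to 800 it was 4 (2%). Support in at least 1 list fell more slowly. Peaks in neither list numbered 13 (6.5%), 60 (30%) and 112 (56%) in these same groups. Of the 143 weakest peaks, 143 were in neither list. The 2 peaks among the first 200 with no partner were the 36.8 kb interval on X at 16343198 to 16380002 and a peak on chromosome I at 7079000 to 7079833 (834 bp, rank 195). The interval on X was the first peak of the series-level list, with a caller value listed as 0.

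**Figure D2:**
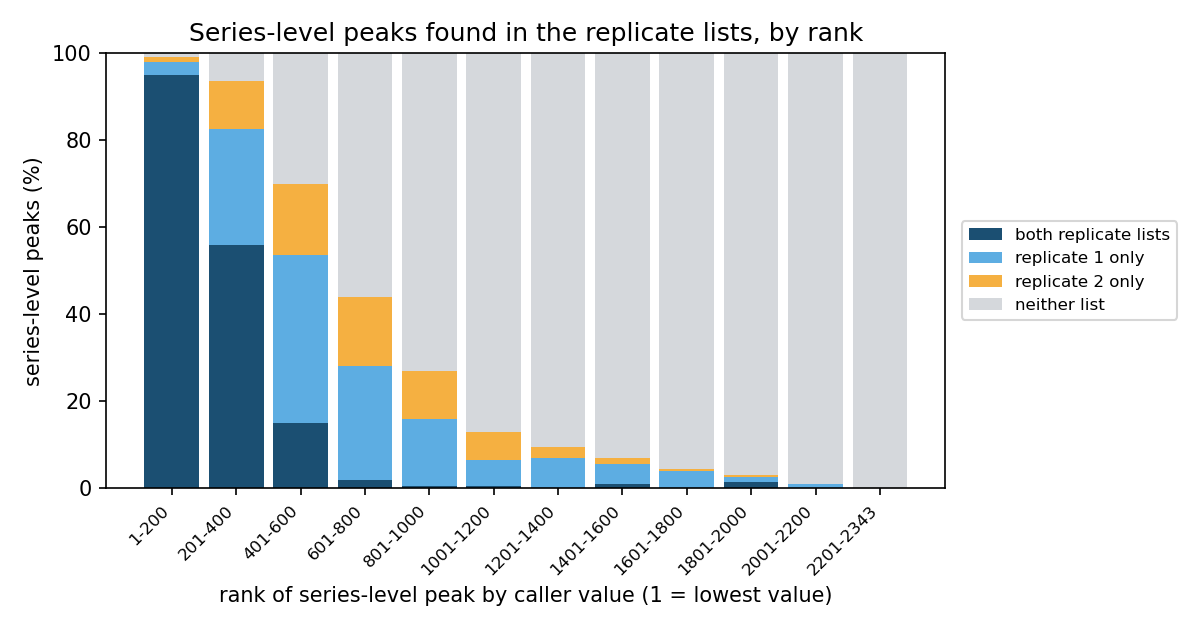
Each bar is a group of up to 200 series-level peaks ordered by caller value, with rank on the x axis and, on the y axis, the percentage found in both replicate lists, in 1 of them or in neither. The share in both lists drops from 95% in the first group to 2% in the fourth.

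The third comparison asked how the sites were spread over the chromosomes. Chromosome III carried the most peaks for its length and chromosome X the fewest, with lengths approximated by the highest peak end and tests chosen after the data were seen. In the series-level list, III held 519 of 2343 peaks (22.2%, interval 20.5 to 23.9%) on 13.8% of the summed length, or 37.7 peaks per Mb (exact binomial test, adjusted p = 2.70e-27). X held 172 peaks (7.34%, interval 6.32 to 8.47%) on 17.5% of the length, or 9.82 peaks per Mb (exact binomial test, adjusted p = 7.65e-46). Peak density on X was 0.372 times that of the autosomes (interval 0.317 to 0.435). The ratio was 0.342 (0.246 to 0.464) in replicate 1 and 0.380 (0.264 to 0.531) in replicate 2, so the deficit on X was much larger than the difference between replicates. Both replicate lists share the strain, the peak caller and the stand-in lengths. An error common to both lists would not show in that difference. The III share was 25.4% in replicate 1 and 23.03% in replicate 2.

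The other autosomes departed less from their length. Chromosome I held 454 peaks (19.4% on 14.98% of the length, exact binomial test, adjusted p = 1.86e-08) and II held 414 (17.7% on 15.3%, adjusted p = 0.0021). Chromosome IV held 361 peaks (15.4% on 17.5%, exact binomial test, adjusted p = 0.0083) and V held 423 (18.1% on 20.9%, adjusted p = 9.86e-04). Of these, the excess on I was not past the threshold of the exact binomial test in replicate 1 (adjusted p = 0.20) or replicate 2 (adjusted p = 0.18) by itself. The deficit on IV was past it in neither replicate (exact binomial test, adjusted p = 0.76 and 0.13), and that on V was past it in replicate 1 alone (adjusted p = 2.64e-04, against 0.22 in replicate 2). Over all 6 chromosomes the distribution differed from length in the series-level list and in each replicate list (Monte Carlo multinomial test of the chi-square statistic with 100000 draws, p = 1e-05 each, the smallest p possible).

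**Figure D3:**
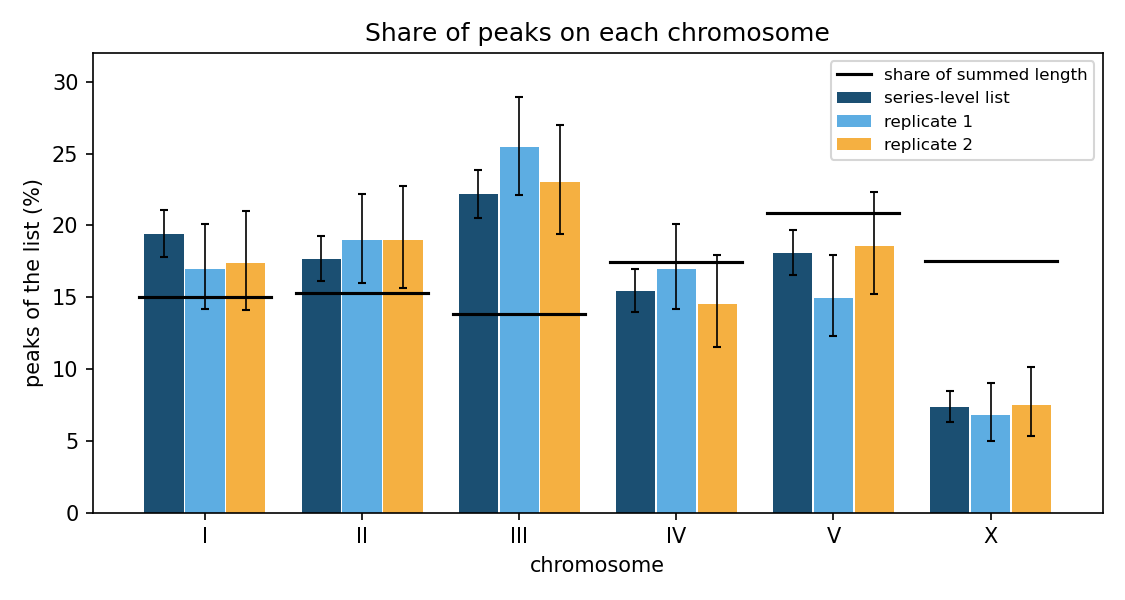
The y axis gives the percentage of a list's peaks on each chromosome of the x axis, for the series-level list, replicate 1 and replicate 2, with 95% Clopper-Pearson intervals as error bars and the chromosome's share of the summed length as a black line. In the 3 lists chromosome III lies above its line and X below it.

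X was better represented among strong peaks than among weak ones. Of the 1171 strongest series-level peaks 114 (9.74%) lay on X, against 58 of the 1172 weakest (4.95%), an odds ratio of 2.07 (95% interval 1.48 to 2.93, Fisher's exact test, p = 8.22e-06). The X share was 15.5% in the first 200 ranks, close to the length share of 17.5%, and 6 of the last 143 peaks lay on X. The first 200 ranks by themselves were not tested against length. The same direction held within each replicate list by Fisher's exact test, with an odds ratio of 2.27 (1.14 to 4.72, p = 0.013) in replicate 1 and 2.53 (1.17 to 5.81, p = 0.010) in replicate 2. X peaks in both replicate lists had higher −log10 caller values in the series-level list, relative to the sum of their replicate values, than autosomal peaks did. The medians of that difference were 4.79 for X and 1.08 for the autosomes, so ranks on X in the series-level list are not on the same footing as ranks on the autosomes.

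No preference for the centres or the arms of the chromosomes was detectable. The middle 50% of each chromosome held 1141 of 2343 series-level peaks (48.7%, interval 46.7 to 50.7%, exact binomial test, p = 0.22). None of the 6 chromosomes taken singly passed the threshold of the exact binomial test in the series-level list (lowest adjusted p = 0.38), with shares from 45.3% on X to 53.2% on V. The centre share was 48.8% in replicate 1 (p = 0.58) and 49.1% in replicate 2 (p = 0.72).

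**Figure D4:**
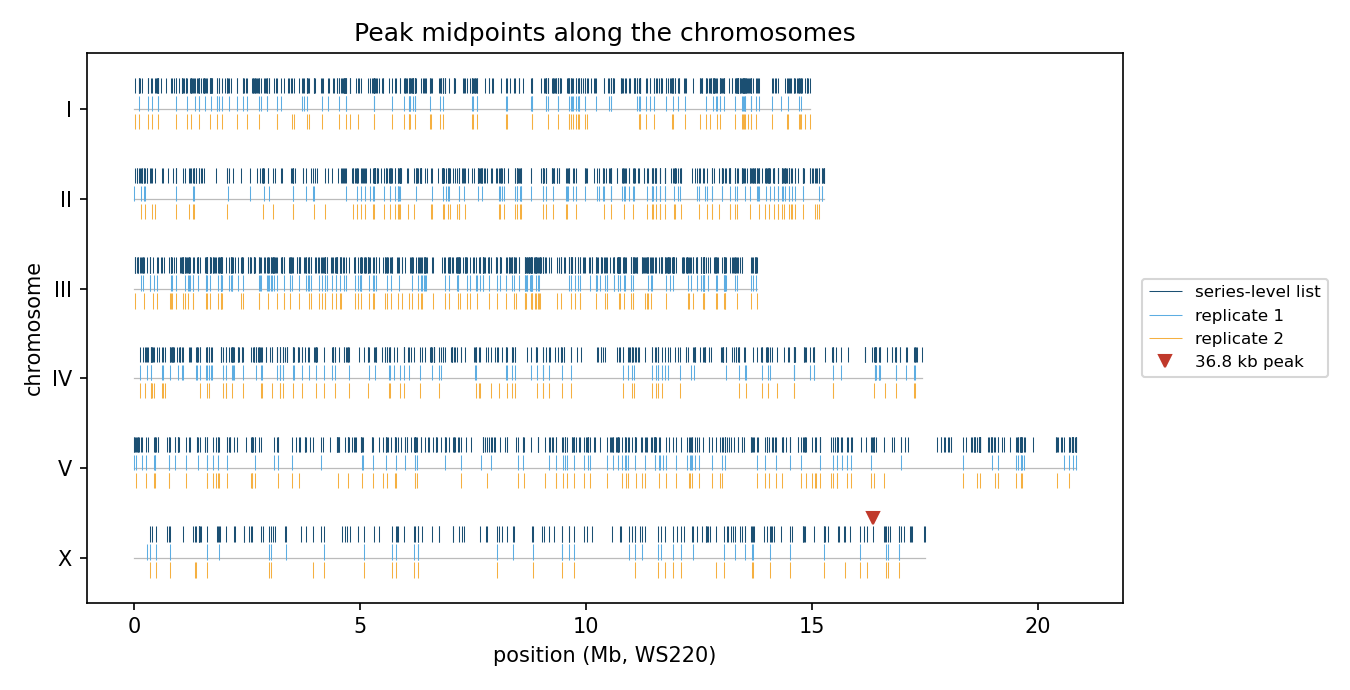
Peak midpoints of the 3 lists are drawn as ticks along each chromosome, with position in Mb on the x axis and the chromosome on the y axis. The red marker shows the 36.8 kb peak on X, and ticks are densest on III and sparsest on X.

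Peaks occurred in neighbourhoods more often than uniform random placement gives. Of the series-level peaks, 795 (33.9%) had another peak midpoint within 5 kb, against a mean of 23.1% for uniform random placement (10000 random draws, one-sided permutation p = 1e-04, the smallest p possible). Within 20 kb the share was 68.1%, against a mean of 63.6% and a highest draw of 68.0%. Uniform placement takes no account of genes or mappable sequence, so the comparison does not show that binding itself is clustered. The densest 20 kb windows were on III at 12597288 to 12617272 and on V at 18704999 to 18724695, with 9 series-level peaks each. The window on III also held 5 replicate 1 peaks and 3 replicate 2 peaks, whereas the window on V held 0 and 1. A window on II at 5320123 to 5338941 held 8 series-level peaks and 1 peak of each replicate. In complete 1 Mb bins, which leave out the last part of each chromosome, the series-level count ranged from 6 to 50 with a median of 22. The fullest bin was on III between 8 and 9 Mb, with 20 peaks of replicate 1 and 15 of replicate 2, and no bin was empty.

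Wide peaks were rare: 11 series-level peaks reached 2000 bp. Chromosome II held 3 of them close together, at 5871477 to 5874516 (3040 bp), 5884907 to 5887636 (2730 bp) and 5889997 to 5893049 (3053 bp). The first and second of these were in both replicate lists and the third was in neither. The wide site on I at 1834594 to 1837431 (2838 bp, caller value 2.06e-23) was in both lists. The wide site on III at 13778074 to 13781241 (3168 bp) was in replicate 2 only, and that on IV at 14620487 to 14622660 (2174 bp) was in neither.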

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

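The tests of shifts of 5 to 50 kb, 10 kb clusters, narrow and very wide peaks, X by rank and neighbourhoods, and all chromosome tests, were chosen after seeing the data. Replicate overlap, value concordance, shared against other peaks, the X and III shares, X by rank and neighbourhoods kept their direction and side of the threshold under the alternatives run. The calls on the other chromosomes did not: among peaks in both replicate lists I, II, IV and V all missed the threshold (exact binomial test, adjusted p = 0.18, 0.13, 0.23 and 0.079), with fewer peaks tested, and with 1 peak per 10 kb cluster so did II and IV (0.17 and 0.059). The share of series-level peaks in both replicate lists was 12.5% when at least 50% of both peaks had to overlap, and 28.9% among the 1171 strongest peaks, which leaves out the weaker peaks that the replicates mostly lack. The X share was 6.78% and 7.47% in the single replicate lists. It was 8.75% among peaks in both replicate lists, 9.74% among the 1171 strongest peaks and 9.73% with 1 peak per 10 kb cluster. These last shares lay above the main interval of 6.32 to 8.47% but below the length share of 17.5%. They do not show a smaller deficit on X. Among peaks in both replicate lists the interval of 5.98 to 12.3% holds the main share of 7.34%. Series-level ranks on X are not on the same footing as those on the autosomes. Keeping 1 peak per 10 kb cluster removes more peaks where they are dense, from 519 to 329 on III but from 172 to 157 on X. The middle 50% of the chromosomes held 47.9% to 52.2%, never past the threshold. Of the 25 named sites, 24 stayed in both replicate lists under the stricter overlap, and III at 10460585 to 10461365 was in 0. No paired analysis was possible because no values of the input libraries were analysed here. Alternatives that need genes or sequence, gene numbers as the expectation included, were not run. Read depth is unknown, so absence from a list does not show absence of binding.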

Other observations

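Of the tests in this part, that of a setting of 1 replicate list alone was written down before its result was seen; those of merging, transgene copies, weak signal, removed rows, fixed ends, held sites with like ends, rank on X, shares without bins and values on X were chosen after related results had been seen.

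Of the 349 sites shared by the replicates, 10 had no partner in the series-level list, the strongest being on IV at 11070896 to 11071324, on I at 933314 to 933712 and on V at 12509901 to 12510294 (ranks 45, 49 and 69 of replicate 1). Their starts and ends together differed between replicates by a median of 2 bp, by 38 bp at the site on IV just named and by at most 5 bp at the other 9. The median was 76 bp for the 339 held sites (difference -74 bp, permutation p = 0.018). DNA segments with fixed ends in both ChIP libraries, such as amplified or cloned DNA, are a candidate explanation for the like ends of those 9. The comparison of ends does not show why the 9 are absent from the series-level list, as 7 sites with ends as close were held. Of the 7 held sites whose ends agreed within 5 bp, 6 had a series-level −log10 value under the sum of their replicate values: the difference had a median of -12.7 over the 7, against 1.26 for the 332 others (-13.9 between them, permutation p = 1e-05), and 3 of the 7 were numbered above 978, the smallest number missing. For sites of this kind, replicate rank therefore says little about series-level strength, and too weak a series-level signal or removal of rows after numbering both stay open, although the median replicate 1 rank differed from that of the held sites by -2.5 and 10 of the 10 had an expected number under 978. Edges of uniquely mappable sequence would leave the same mark and stay open too, and no biological explanation was tested.

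The first peak of the series-level list, on X at 16343198 to 16380002, was 36805 bp wide, 11.6 times the next widest, and neither replicate list had a peak inside it. Merging of neighbouring ordinary peaks stays open: 79.8 peaks of median width at the smallest gap in the list, 209 bp, would fill the interval and the densest other window of that length held 10, but if closer peaks were joined, a step not given in the sources used here, no other window could be packed as tightly. Extra copies of the transgene's DNA in the strain are another candidate explanation, as nhr-28 lies on X. This cannot be told apart from other sources: such copies would be in every library, the replicate lists lack the interval, and neither the position of nhr-28 on this build nor input coverage was used here.

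A replicate list held 29.1% of the series-level peaks on X and 31.9% of the autosomal ones, a difference short of the threshold (Fisher's exact test, p = 0.50), but 50 of 172 is fewer than the 78.3 expected from autosomal and X peaks in the same bins of 200 series-level ranks (stratified permutation, p = 2e-05, the smallest p possible). Over the 343 peaks in all 3 lists, the series-level −log10 value minus the sum of the replicate values had a median of 4.79 on X and 1.08 on the autosomes, a difference of 3.72 that was 3.65 within 5 bins of like replicate values (permutation p = 1e-05 for each). Values set differently on X between the series-level list and the replicate lists are a candidate explanation. A background scaled per chromosome would be an example, a step not given in the sources used here. The higher values on X and the shortfall at like series-level rank are not independent. The higher values are therefore not separate support for that explanation. Because series-level values on X stood higher relative to replicate values, whatever the reason, like series-level rank is not like replicate strength, and lower strength of the X peaks stays open; a setting of 1 replicate list alone is argued against, since the shortfall was in both lists (43 against 67.1 expected in replicate 1 and 37 against 55.8 in replicate 2, stratified permutation, p = 2e-05 each), while without bins the shares were 25% against 26.1% and 21.5% against 20.3%. The lower peak density on X was found in each replicate list too, and no biological explanation was tested.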
